A study of Mus musculus with 16 samples.

How the data were processed

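Gene expression was measured in mouse blastocysts, the embryo stage at which an outer trophectoderm surrounds the inner cell mass and a fluid cavity. Per the labels, total RNA came from blastocysts treated with 20 µM SB203580, 25 µM SP600125 or 20 µM U0126, or from blastocysts for which no treatment is named, which served as the control group. The labels do not state whether these controls received the solvent of the inhibitors. SB203580 is used as an inhibitor of p38 MAP kinases, SP600125 of JNK and U0126 of MEK, the kinase that activates ERK. The 12 samples formed 4 groups of 3 replicates and were read on 16 Affymetrix arrays. Replicate 1 of each group was labelled by the small sample assay and hybridised to a 430A and a 430B array, which were joined into 1 sample by their label number, and replicates 2 and 3 were labelled by the two-cycle assay and hybridised to 430 2.0 arrays. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples.

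The deposited values are signal intensity on a linear scale, 1 per probe set, and each array had been scaled by the authors so that its mean, with 2 percent trimmed at each end, was 500. The software, the background correction and the probe summary are not given in the sources used here. The scaling was checked on every array. Values were kept on the deposited scale, 12.6 was added (the 20th percentile of the 430 2.0 values) and the log2 was taken. Affymetrix control probe sets were left out of the tests. Of 45037 probe sets measured in all samples, 34945 named 1 gene in the platform annotation, 932 named several and 9160 named none in the annotation used. Probe sets were tested if their mean over the 430 2.0 arrays reached the 40th percentile of such means, which left 27022 probe sets, of which 22539 named 1 gene, for 12601 genes. The 164 probe sets present on both the 430A and the 430B array entered once. Array signal carries no count, and the number of arrays limits the precision.

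Each of 6 comparisons (each inhibitor against the control group, and each pair of inhibitors) was tested with limma 3.58.1 in R 4.3.3. The linear model had the 4 groups and the array type with its labelling assay as a fixed block, so that every difference was taken within arrays of 1 type. Moderated statistics used an intensity trend, with 7 residual degrees of freedom and a median of 9.7 prior degrees of freedom. P-values are two-sided and Benjamini-Hochberg adjusted over the probe sets tested, with calls at an adjusted p under 0.05. Errors are standard errors of the log2 change, with n = 3 samples per group. Replicate differences and replicate medians in the text take each sample from the mean of the compared group on the same array type. In simulated data for U0126 against control, 40 percent of changes of log2 1 and 84 percent of changes of log2 2 were recovered, with 5 false calls. The simulated noise was independent between probe sets and normal, with the spread that the fitted model gave. Recovery and false calls in the real data can therefore differ.

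Of 25 gene lists, 24 had the minimum of 5 tested genes and were tested against all other genes with limma's camera, with a preset correlation between genes of 0.01, 1 probe set per gene (the brightest) and adjustment over the lists of a comparison. They covered trophectoderm, inner cell mass and epiblast, and primitive endoderm markers, immediate early genes, ERK output, MAP kinase pathway, blastocoel formation, actin and SRF targets, heat shock, NRF2, aryl hydrocarbon receptor, amino acid response, unfolded protein response, p53, G2 and M phase, G1 to S, cholesterol synthesis, glycolysis, lysosome, ribosome biogenesis, oocyte, cleavage stage, cumulus and granulosa cell, uterine and oviduct epithelium, and blood and immune cell genes. The last list kept 4 of its 13 genes and was not tested. Camera was also run with the correlation estimated from the data, and fry was run beside it. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

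Genes were named by rule. These were the 8 largest rises and the 8 largest falls of each inhibitor against control among called genes that moved the same way in all 3 replicates, each ranked by the brightest of its called probe sets on the 430 2.0 arrays, up to 4 called members of each list, the 4 members with the largest absolute moderated t of each list called by camera, and the genes of the target kinases (Mapk14, Mapk11, Mapk8, Mapk9, Map2k1 and Map2k2). For pairs of inhibitors, the 3 largest called differences in each direction were taken. A fallback for comparisons with fewer than 5 called genes was not needed. The groups, tests, lists, named-gene rule and most alternative settings were chosen before the data were examined. The list tests for pairs of inhibitors, a setting without probe sets ending in _x_at or _s_at, and 3 further lists (Nodal and TGF-beta targets, Wnt targets, imprinted genes, the last with and without Grb10) were chosen after seeing the data.

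The alternatives were quantile normalisation, pseudocounts at other percentiles, no filter or a stricter one, a replicate block, no intensity trend, array weights, the mean of a gene's probe sets, and leaving out each sample or each replicate number in turn. Changes against the shared controls were also compared with 100 simulations of unchanged groups that shared the same controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.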

Results

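Expression was compared across 12 blastocyst samples, 3 each for the control group and for treatment with SB203580, SP600125 or U0126. On the 430 2.0 arrays, which hold replicates 2 and 3, the median signal was 61.1 and 65.7 in the controls, 66.2 and 68.9 with SB203580, 61.5 and 66.5 with SP600125, and 77.7 and 83.0 with U0126. The 430A arrays of replicate 1 had medians from 131.6 to 147.4 and the 430B arrays from 223.8 to 230.9. The ratio of 3' to 5' actin signal, a sign of RNA quality and labelling length, lay between 1.58 and 1.75 on the 430 2.0 arrays. On the 430A arrays it was 2.47 in the control, 2.81 with SB203580, 3.66 with SP600125 and 1.62 with U0126. The GAPDH ratio over all arrays ranged from 2.61 to 4.80. Correlations of log2 signal between samples were 0.935 to 0.966 within an array type and 0.6998 to 0.740 across types. The number of probe sets called in each of the 6 comparisons ran from 105 to 783.

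**Figure D1:**
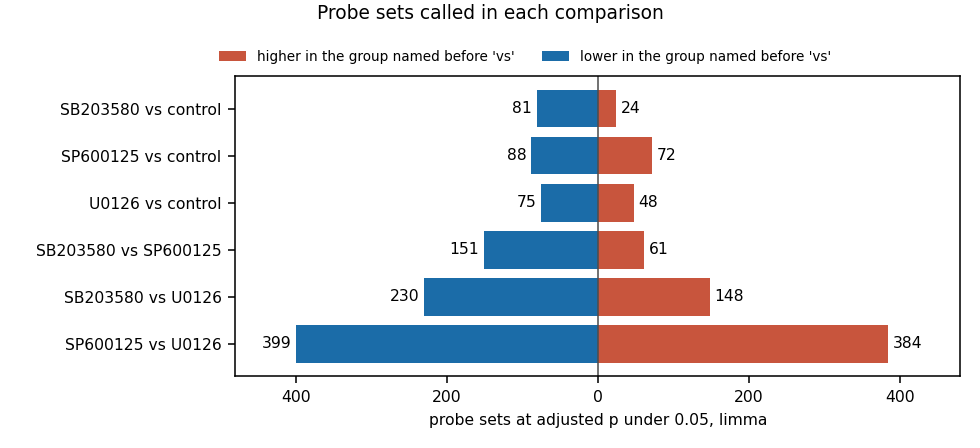
Number of probe sets at an adjusted p under 0.05 (limma, 3 samples per group) in each comparison, with bars to the right for probe sets higher and to the left for those lower in the first group named. SP600125 against U0126 had 384 higher and 399 lower.

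The first comparison asked what SB203580, the p38 inhibitor, changed in blastocysts. The cholesterol synthesis genes that fell were Fdft1, which makes squalene (-1.06 ± 0.13, log2 change ± SE, n = 3), Cyp51, which removes a methyl group from lanosterol (-1.17 ± 0.17), and Nsdhl (-0.82 ± 0.12). Of the primitive endoderm markers, Amn, a part of the cubilin receptor of absorptive epithelia, fell (-1.80 ± 0.26). Mapkapk3, which encodes a kinase that p38 phosphorylates, fell by 1.52 on the log2 scale (SE 0.22, adjusted p = 0.00392). Among the largest falls were Lefty2 (-2.88 ± 0.47), with Lefty1 at -2.01 ± 0.42, and Ctsll3, a cathepsin-like protease gene (-3.32 ± 0.57). Both Lefty genes encode antagonists of Nodal. The size for Ctsll3 rests on replicate 1, where the SB203580 signal of 4.8 lay under the added constant. Differences of replicates 1, 2 and 3 from the control mean of their array type were -5.92, -2.18 and -1.85. The change ranged from -4.29 to -2.01 over the settings and omissions.

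Further falls were Papss2, which makes the sulphate donor of the cell (-2.63 ± 0.41), the apolipoprotein gene Apoa1 (-2.53 ± 0.48), Arhgap27 (-2.23 ± 0.38), the homeobox gene Cdx1 (-2.07 ± 0.35) and Dkk1, a secreted Wnt antagonist (-1.87 ± 0.28). The largest rises were Ap5z1 (2.89 ± 0.43) and Spic, a transcription factor of the Ets family (2.22 ± 0.28). Control signals of Ap5z1 on the 430 2.0 arrays were 9.9 and 12.9, near the added constant. Of its 5 probe sets 4 had the same sign and 1 was called. Egr1, an immediate early transcription factor, rose by 1.86 ± 0.37. Becn2 (1.64 ± 0.27), Cd24a (1.57 ± 0.33), Lrsam1 (1.47 ± 0.29), Lpcat1 (1.31 ± 0.26) and the keratin gene Krt19 (1.26 ± 0.25) were the other rises named.

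By list, 3 of 19 cholesterol synthesis genes fell with SB203580, or 12 adjusted over the list alone, and none rose. Their median change was -0.51 (adjusted p = 7.99e-13), and it was -0.34, -0.52 and -0.49 in replicates 1, 2 and 3. Of 21 primitive endoderm markers 1 fell, or 11 adjusted over the list alone, with a median of -0.51 (adjusted p = 1.79e-10). Lama1 (-0.85 ± 0.21), Sox7 (-1.14 ± 0.28) and Sparc (-0.66 ± 0.16) did not pass on their own. Trophectoderm markers had a median of -0.16 over 16 genes (adjusted p = 0.000756), while the 1 member that passed over all genes, Krt19, rose, and 4 were lower adjusted over the list alone. Elf5 (-1.0 ± 0.23), Krt7 (-0.59 ± 0.15) and Gata3 (-0.63 ± 0.17), which did not pass, had the next largest statistics. The median of actin and SRF targets was -0.22 (adjusted p = 0.000544), and 1 of 18 fell, Cnn2, which encodes a calponin (-0.77 ± 0.15), or 2 adjusted over the list alone. Srf itself stood at -0.71 ± 0.19 and did not pass, with Vcl at -0.38 ± 0.13 and Fhl2 at -0.71 ± 0.27. These 4 lists kept their calls with an estimated correlation, but with larger p-values. The adjusted p was then 0.0302 for the cholesterol, primitive endoderm and actin lists and 0.031 for trophectoderm markers.

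Another 3 lists were called for SB203580 with the preset correlation alone. Amino acid response genes had a median of -0.22 (adjusted p = 0.000544), with 0 of 21 past the test, 2 lower adjusted over the list alone, and an adjusted p = 0.202 with an estimated correlation. Mthfd2 (-0.71 ± 0.18) and Slc7a3 (-0.65 ± 0.19) were its leading members. The call was lost without replicate 1, at a median of -0.13 and an adjusted p = 0.0616. Genes of the unfolded protein response had a median of -0.25 (adjusted p = 0.000544), none past the test, and an adjusted p = 0.214 with an estimated correlation. Lysosome genes had a median of 0.19 (adjusted p = 0.00375), none past the test, and an adjusted p = 0.0686 with an estimated correlation. Without replicate 2 the lysosome list stood at 0.14 (adjusted p = 0.067).

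In all, 105 of 27022 probe sets passed for SB203580, 24 higher and 81 lower, for 21 and 67 genes, and 2526 had an unadjusted p under 0.05 where 1351 would be expected by chance. On the 430 2.0 arrays alone, 35 were called, and 34 of these moved the same way in replicate 1 (97.1 percent, against 56.8 percent of all tested). The count was 33 without control replicate 1, 46 without control replicate 2, 52 without SB203580 replicate 2 and 41 without SB203580 replicate 3. Of 22 called genes named for SB203580, 8 kept their calls when any single sample was left out. These were Ap5z1, Spic, Papss2, Amn, Mapkapk3, Cyp51, Fdft1 and Nsdhl. The other named calls were lost in at least 1 such omission. Each omission also leaves fewer samples, so a lost call need not rest on the sample left out.

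The second comparison asked what SP600125, the JNK inhibitor, changed. Primitive endoderm markers fell furthest as a group, including the basement membrane genes Lama1 (-1.65 ± 0.21, log2 change ± SE, n = 3), Col4a2 (-1.47 ± 0.17) and Col4a1 (-1.33 ± 0.16), the matrix gene Sparc (-1.26 ± 0.16), and the endocytic receptor pair Cubn (-2.19 ± 0.37) and Amn (-1.60 ± 0.26). Of the transcripts normally abundant at cleavage stages, Usp17la (2.87 ± 0.41), Tcstv1 (2.55 ± 0.51) and Zfp352 (2.29 ± 0.45) rose. Cholesterol synthesis genes including Idi1 and Sqle fell, and the p53 target Plk2, a polo-like kinase gene, rose (2.36 ± 0.40).

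Of 21 primitive endoderm markers 12 fell with SP600125, or 15 adjusted over the list alone, with a median of -1.26 (adjusted p = 4.57e-25) and replicate medians of -1.05, -1.06 and -1.26. Srgn was among them (-1.84 ± 0.30), as was Foxa2 (-1.33 ± 0.28), which also stands on the list of uterine and oviduct epithelium. Of the 21 markers, 18 had negative and 3 positive values. Gata6 did not fall on the probe set named for U0126. Its signals were 2719.6, 4895 and 5088.3 in controls and 3815.4, 5278.8 and 5178.5 with SP600125. Replicate 1 with SP600125 had the highest actin 3' to 5' ratio of the 430A arrays, 3.66 against 2.47 in its control. Of 16 listed cleavage stage transcripts 7 were tested, and 3 of these rose, or 5 adjusted over the list alone. The median of the 7 was 1.96 (adjusted p = 7.88e-09), with replicate medians of 1.42, 1.76 and 2.02. Spz1, which stood at that median (1.96 ± 0.62), did not pass. The signal filter averages the 430 2.0 arrays of all groups, so members raised by SP600125 passed it more easily. Tcstv1 had signals of 6.8 to 74.7 on the other 430 2.0 arrays, against 242.5 and 374.7 with SP600125. The list kept its call in all 20 settings and omissions that tested it, with medians from 1.14 to 2.32. The signals were low in controls, 57.0 to 195.4 for Usp17la against 638.8 to 1318.5 with SP600125. Of 19 cholesterol synthesis genes 6 fell, or 12 adjusted over the list alone, with a median of -0.54 (adjusted p = 4.96e-16) and replicate medians of -0.42, -0.71 and -0.63. Cyp51 (-1.0 ± 0.17), Idi1 (-0.84 ± 0.13), Fdft1 (-0.78 ± 0.13) and Sqle, which encodes squalene epoxidase (-0.74 ± 0.12), were among them. These 3 lists kept their calls with an estimated correlation, but with larger p-values. The adjusted p was then 0.00656 for primitive endoderm markers and 0.0104 for both the cleavage stage and the cholesterol list.

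The p53 targets had a median of 0.49 over 14 genes (adjusted p = 2.96e-07), with 2 risen, or 6 higher and 1 lower adjusted over the list alone. The adjusted p = 0.0832 with an estimated correlation. Replicate medians were 0.01, 0.53 and 0.75. Plk2 and Btg2, an antiproliferative gene (1.17 ± 0.22), rose. Ccng1 rose on 1 probe set (0.83 ± 0.17) and stood at 0.86 ± 0.19 on the brighter one (adjusted p = 0.0542). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.86 ± 0.23 and did not pass. Amino acid response genes had a median of -0.27 (adjusted p = 6.73e-05), with 3 of 21 fallen, or 4 adjusted over the list alone. Their adjusted p = 0.123 with an estimated correlation. These were Chac1, a glutathione-degrading enzyme gene (-1.48 ± 0.27), the stress-response gene Nupr1 (-1.46 ± 0.20) and Phgdh of serine synthesis (-0.68 ± 0.15). Heat shock genes had a median of 0.15 (adjusted p = 0.0122), none past the test, and an adjusted p = 0.0832 with an estimated correlation. Hspa1b, at 0.83 ± 0.26, was the leading member.

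For SP600125, 4 lists with small medians lost their calls without single samples. G2 and M phase genes had a median of 0.12 (adjusted p = 0.00907, and adjusted p = 0.182 with an estimated correlation), and glycolysis genes -0.14 (adjusted p = 0.0164, and adjusted p = 0.123 with an estimated correlation). No member of either passed over all genes, and 2 glycolysis genes were lower adjusted over the list alone. Without control replicate 1 they stood at 0.04 and -0.11 (adjusted p = 0.29 for each), and without SP600125 replicate 1 at 0.08 and -0.16 (adjusted p = 0.114 for each). Lysosome genes had a median of 0.06 (adjusted p = 0.0363, and adjusted p = 0.14 with an estimated correlation), with 1 of 17 risen, the membrane protein gene Lamp2 (0.82 ± 0.17), or 3 adjusted over the list alone. Ctsb, a member of the same list, fell on 1 dim probe set of 5 (-2.17 ± 0.47, adjusted p = 0.0477), and 4 of the 5 had the same sign, while its brightest probe set, the one in the list test, stood at -0.09 ± 0.17. Ribosome biogenesis genes had a median of -0.14 (adjusted p = 0.0363, and adjusted p = 0.332 with an estimated correlation). Without control replicate 2 these lists stood at 0.04 (adjusted p = 0.0976) and -0.10 (adjusted p = 0.117), and without SP600125 replicate 1 at 0.02 (adjusted p = 0.228) and -0.06 (adjusted p = 0.576). The lysosome list was also lost without SP600125 replicate 2, at 0.07 (adjusted p = 0.0531). On the 430 2.0 arrays alone, all 4 lists were lost, with medians of 0.02, -0.06, 0.06 and -0.08 (adjusted p = 0.42, 0.409, 0.129 and 0.42).

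Outside the called lists, the largest rises with SP600125 were AF067061 (4.75 ± 0.73), BC080696 (4.21 ± 0.42), Gm11544 (3.74 ± 0.50), Gm20767 (3.49 ± 0.74), D13Ertd608e (2.74 ± 0.36) and the axon guidance receptor gene Robo1 (2.68 ± 0.46). Control signals for AF067061 ran from 8.5 to 148.2, so its change depends on the added constant. Falls included the forkhead gene Foxq1 (-2.10 ± 0.25), Cdx1 (-1.90 ± 0.35), the BMP-binding protein gene Bmper (-1.86 ± 0.32), the water channel gene Aqp8 (-1.45 ± 0.15), the ERK phosphatase gene Dusp4 (-1.41 ± 0.23), the trophoblast factor Elf5 (-1.14 ± 0.23) and the glutathione transferase gene Gsta4 (-0.53 ± 0.11). Krt19 (1.18 ± 0.25), the autophagy receptor gene Sqstm1 (0.54 ± 0.12) and Laptm5 (1.33 ± 0.25) rose, the last on 1 of 4 probe sets, of which 2 had the same sign. Laptm5 belongs to the blood and immune cell list. Dkk1 fell on both of its probe sets, with -2.02 ± 0.28 on the dimmer one (adjusted p = 0.00189) and -1.29 on the brighter one (adjusted p = 0.0465), which set its rank.

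In all, 160 probe sets passed for SP600125, 72 higher and 88 lower, for 50 and 69 genes, and 2293 had an unadjusted p under 0.05 where 1351 would be expected. On the 430 2.0 arrays alone, 80 were called, of which 76 moved the same way in replicate 1 (95.0 percent, against 55.9 percent of all tested). The count was 86, 89 and 80 without control replicate 1, 2 or 3, and 92, 91 and 76 without SP600125 replicate 1, 2 or 3. Without control replicate 1 the balance turned to 46 higher and 40 lower. Of 39 called genes named for SP600125, 15 kept their calls when any single sample was left out. Among them were BC080696, Foxq1, Aqp8, Col4a1, Col4a2, Lama1, Sparc, Usp17la, Nupr1, Idi1, Fdft1 and Sqle. The other named calls were lost in at least 1 such omission, which also leaves fewer samples.

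The third comparison asked what U0126, the MEK inhibitor, changed. The feedback phosphatases of ERK signalling fell, Dusp6 by 2.26 ± 0.29 (log2 scale, SE, n = 3) and Dusp4 by 2.12 ± 0.23. Cyp1a1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose by 4.46 ± 0.62. Epiblast genes Fgf4 (1.30 ± 0.20), a growth factor made by the inner cell mass, and Sox2 (0.87 ± 0.14) rose. Of the primitive endoderm markers, Gata6, a transcription factor of that lineage (-0.60 ± 0.12), and Amn (-1.53 ± 0.26) fell.

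Of 15 ERK output and feedback genes 2 fell with U0126, or 5 adjusted over the list alone, with a median of -0.38 (adjusted p = 4.99e-06) and replicate medians of -0.57, -0.28 and -0.49. The median ranged from -0.45 to -0.15 over the settings and omissions, weakest with the mean of a gene's probe sets. Spry4 (-1.80 ± 0.44) and Phlda1 (-1.03 ± 0.27) did not pass. All 21 primitive endoderm markers had negative values, 2 passed, or 11 adjusted over the list alone, and the median was -0.53 (adjusted p = 2.75e-14). Sparc (-0.70 ± 0.16) and Sox17 (-0.87 ± 0.21) did not pass. G1 to S and replication genes had a median of -0.23 (adjusted p = 5.15e-07), with 1 of 21 fallen, or 6 adjusted over the list alone. It was Rrm1, a subunit of ribonucleotide reductase (-0.63 ± 0.11), with Mcm5 at -0.37 ± 0.08 and Cdc6 at -0.55 ± 0.13 short of the threshold. Lysosome genes had a median of 0.21 (adjusted p = 0.00019), with 1 of 17 risen over all genes and also adjusted over the list alone, the sialidase gene Neu1 (0.74 ± 0.16). These 4 lists kept their calls with an estimated correlation, but with larger p-values. The adjusted p was then 0.0118 for the ERK output, primitive endoderm and G1 to S lists and 0.0297 for lysosome genes. U0126 replicate 1 had the lowest actin 3' to 5' ratio of the 430A arrays, 1.62.

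The other lists called for U0126 lost their calls with an estimated correlation. Of 5 aryl hydrocarbon receptor targets 1 rose, or 3 adjusted over the list alone, with a median of 2.27 (adjusted p = 0.00189, and adjusted p = 0.105 with an estimated correlation). Cyp1b1 was at 3.33 ± 0.75 (adjusted p = 0.0666) and the repressor gene Ahrr at 2.27 ± 0.56 (adjusted p = 0.0915), while the other 2 members, Nqo1 (-0.27 ± 0.58, adjusted p = 0.899) and Tiparp, did not rise. With so few members the median ranged from 0.44, without the filter on dim probe sets, to 2.73. Only 5 of 8 listed genes were tested, and the filter averages the 430 2.0 arrays of all groups, U0126 included. Members raised by U0126 passed it more easily, so the median of the tested members can overstate that of the list. Cyp1b1 had signals of 1.5 to 58.9 on the other 430 2.0 arrays, against 589.9 and 689.7 with U0126. Of 19 inner cell mass and epiblast markers 2 rose, or 6 adjusted over the list alone, with a median of 0.20 (adjusted p = 0.00581, and adjusted p = 0.195 with an estimated correlation). Esrrb, at 1.26 ± 0.29, and Klf2, at 0.80 ± 0.25, did not pass. That list stood at 0.27 without U0126 replicate 1 (adjusted p = 0.0843) and at 0.17 on the 430 2.0 arrays alone (adjusted p = 0.0933). Of 16 unfolded protein response genes 3 fell, or 8 adjusted over the list alone, with a median of -0.36 (adjusted p = 4.11e-07, and adjusted p = 0.0801 with an estimated correlation). They were the chaperone gene Hspa5 (-0.64 ± 0.12), Manf (-0.66 ± 0.13) and Pdia6 (-0.68 ± 0.14), and 2 of the 3 Hspa5 probe sets had the same sign. G2 and M phase genes had a median of -0.13 (adjusted p = 0.00019, and adjusted p = 0.105 with an estimated correlation), with 0 past the test and 2 lower adjusted over the list alone, led by Ccna2 (-0.53 ± 0.13). For p53 targets the median was -0.25 (adjusted p = 0.0292, and adjusted p = 0.375 with an estimated correlation), with 0 past the test and 1 higher and 1 lower adjusted over the list alone. Ei24, at 0.47 ± 0.13, and Ccng1, at -0.67 ± 0.19, were leading members. The p53 list was lost without control replicate 1 (median -0.16, adjusted p = 0.139), U0126 replicate 2 (-0.16, 0.185) or U0126 replicate 3 (-0.15, 0.145).

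Further rises with U0126 were the protease gene Klk7 (2.46 ± 0.21, adjusted p = 3.07e-05), Ap5z1 (2.58 ± 0.43), the tight junction gene Cldn9 (2.48 ± 0.48), Ndrg4 (2.27 ± 0.28), Tgfbi (2.03 ± 0.33), Eva1b (1.58 ± 0.23), Patl2 (1.33 ± 0.22), Krt19 (1.20 ± 0.25) and the glucose transporter gene Slc2a1 (0.80 ± 0.16). Falls included C8g (-2.25 ± 0.47), Papss2 (-2.09 ± 0.41), Tspan1 (-1.99 ± 0.21), Bmper (-1.86 ± 0.32), the uroplakin gene Upk1b (-1.67 ± 0.25) and Vim, which encodes vimentin (-1.60 ± 0.32). Ccn1, a matrix protein gene and an immediate early gene (-1.46 ± 0.24), the sodium pump subunit gene Atp1b1 (-0.59 ± 0.11) and Nsdhl (-0.74 ± 0.12) also fell. Cholesterol synthesis genes as a list were not called for U0126, with a median of -0.16 (adjusted p = 0.0535) and 1 of 19 fallen.

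In all, 123 probe sets passed for U0126, 48 higher and 75 lower, for 39 and 63 genes, and 3230 had an unadjusted p under 0.05 where 1351 would be expected. On the 430 2.0 arrays alone, 51 were called, of which 47 moved the same way in replicate 1 (92.2 percent, against 53.7 percent of all tested). The count was 62, 54 and 74 without control replicate 1, 2 or 3, and 53 and 61 without U0126 replicate 2 or 3. Of 30 called genes named for U0126, 9 kept their calls when any single sample was left out. These were Cyp1a1, Klk7, Ndrg4, Eva1b, Dusp6, Dusp4, Tspan1, Upk1b and Fgf4. The other named calls were lost in at least 1 such omission, which also leaves fewer samples.

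**Figure D2:**
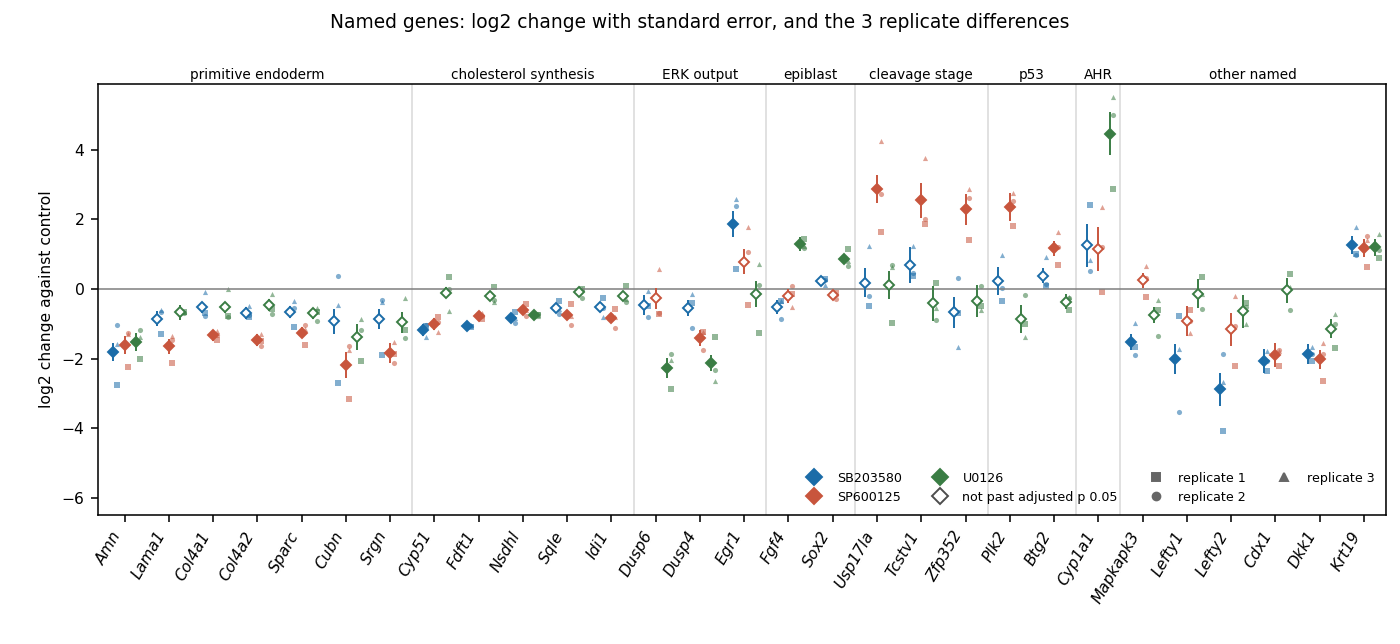
Log2 change against control (vertical axis) of selected named genes for each inhibitor. Diamonds with bars are fitted changes with standard errors, filled where the adjusted p was under 0.05, and small marks are the differences from the control of the same replicate number in replicates 1, 2 and 3. Dusp6 was at -2.26 with U0126, and Plk2 at 2.36 with SP600125.

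The remaining lists were not called against control for any inhibitor. In the order SB203580, SP600125 and U0126, the medians were -0.07, 0.05 and 0.05 for immediate early genes, 0.02, 0.04 and 0.03 for MAP kinase pathway genes, 0.05, 0.00 and 0.05 for blastocoel genes, and 0.07, 0.18 and 0.05 for NRF2 targets. They were 0.00, -0.12 and 0.07 for oocyte transcripts, 0.18, 0.19 and 0.52 for cumulus and granulosa cell markers, and -0.36, 0.02 and -0.37 for uterine and oviduct epithelium markers. Where other lists were called for 1 or 2 inhibitors, the uncalled medians for SB203580 were 0.06 for epiblast, -0.06 for ERK output, -0.01 for heat shock, -0.32 for aryl hydrocarbon receptor, -0.13 for p53, 0.10 for G2 and M phase, 0.01 for G1 to S, -0.09 for glycolysis, 0.00 for ribosome biogenesis and 0.18 for cleavage stage genes. For SP600125 they were 0.06 for trophectoderm, -0.02 for epiblast, -0.24 for ERK output, -0.04 for actin, -0.05 for aryl hydrocarbon receptor, -0.01 for unfolded protein response and -0.05 for G1 to S genes. For U0126 they were 0.06 for trophectoderm, 0.05 for actin, 0.05 for heat shock, 0.09 for amino acid response, -0.02 for glycolysis, 0.02 for ribosome biogenesis and -0.33 for cleavage stage genes. The sign of the median, the mean and the test differed in 4, 4 and 5 of the 24 lists, none of them called. The target kinase genes Mapk14, Mapk8, Mapk9, Map2k1 and Map2k2 did not pass for any inhibitor, with values between -0.37 and 0.16, and Mapk11 did not reach the signal filter.

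**Figure D3:**
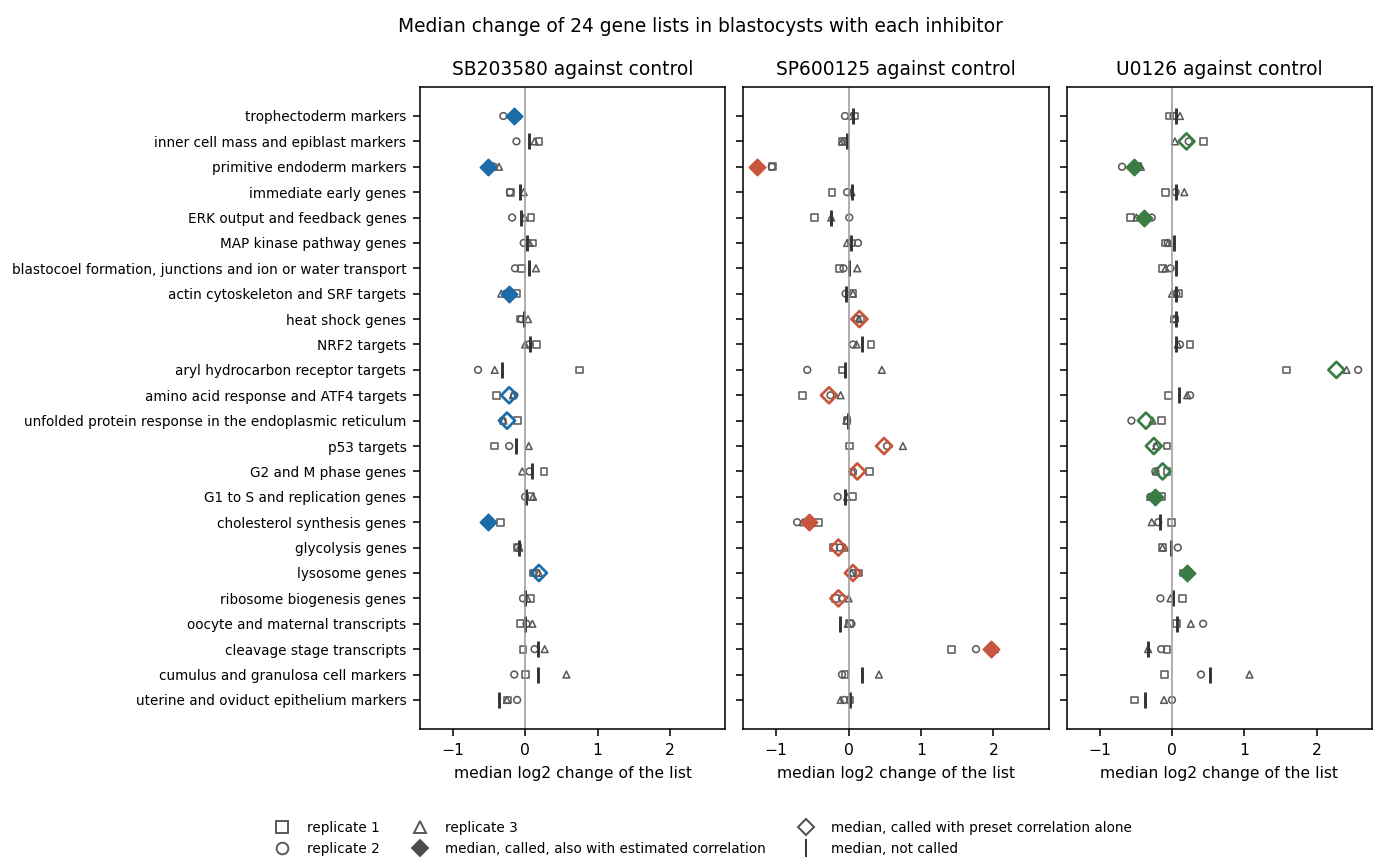
Median log2 change (horizontal axis) of 24 gene lists for each inhibitor against control. Diamonds are called lists, filled where the call held with an estimated correlation, vertical ticks are uncalled lists, and open squares, circles and triangles are the medians in replicates 1, 2 and 3. Primitive endoderm markers were at -0.51, -1.26 and -0.53.

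Direct comparisons asked where the inhibitors differed from each other, with 8 lists called for SB203580 against SP600125, 9 for SB203580 against U0126 and 11 for SP600125 against U0126, of which 4, 3 and 3 kept their calls with an estimated correlation. For SB203580 against SP600125 the 4 were trophectoderm markers (median -0.24, 1 of 16 lower, adjusted p = 1.38e-05), actin and SRF targets (-0.24, 1 of 18 lower, adjusted p = 0.000842), p53 targets and cleavage stage transcripts. With an estimated correlation the trophectoderm, actin and p53 lists each had an adjusted p = 0.0324 here. SP600125 gave higher p53 targets and cleavage stage transcripts than either other inhibitor. Relative to SB203580, 5 of 14 p53 targets were higher with SP600125 (median of SB203580 minus SP600125 -0.78, adjusted p = 6.65e-10), and relative to U0126 7 were higher (median 0.71, adjusted p = 7.05e-07). The second call had an adjusted p = 0.0692 with an estimated correlation. Cleavage stage transcripts differed by -1.86 between SB203580 and SP600125 (adjusted p = 6.03e-06) and by 2.61 between SP600125 and U0126 (adjusted p = 7.96e-07, 5 of 7 higher). Primitive endoderm markers were 0.59 higher with SB203580 than with SP600125 (adjusted p = 6.03e-06, 3 of 21 higher), with an adjusted p = 0.0775 with an estimated correlation. Between SP600125 and U0126 they differed by -0.57 (adjusted p = 0.00188), with 4 lower and Gata6 higher, and the adjusted p = 0.149 with an estimated correlation.

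ERK output genes were higher with SB203580 than with U0126 (6 of 15 higher, median 0.22, mean 0.65, adjusted p = 1.77e-05), and Egr1 differed by 2.01 ± 0.37. The difference of SP600125 from U0126 on this list was 0.51 (adjusted p = 0.00442), with 1 gene higher and 1 lower, and the adjusted p = 0.0692 with an estimated correlation; on replicates 1 and 3, without replicate 2, it was 0.26 (adjusted p = 0.0755). G2 and M phase genes were higher than with U0126 by 0.28 for SB203580 (adjusted p = 1.9e-07) and 0.31 for SP600125 (adjusted p = 3.44e-07), and G1 to S genes by 0.24 (adjusted p = 1.9e-07) and 0.16 (adjusted p = 0.000423). Cholesterol synthesis genes were lower than with U0126 by medians of -0.36 for SB203580 (3 of 19 lower, adjusted p = 4.35e-06) and -0.44 for SP600125 (6 of 19 lower, adjusted p = 4.37e-06). The cholesterol values had an adjusted p = 0.0613 and an adjusted p = 0.0751 with an estimated correlation. Aryl hydrocarbon receptor targets were lower than with U0126 by -2.14 for SB203580 (adjusted p = 0.000168, and adjusted p = 0.0601 with an estimated correlation) and by -2.32 for SP600125 (adjusted p = 0.0105, and adjusted p = 0.149 with an estimated correlation). Without U0126 replicate 3 the second difference was -2.22 (adjusted p = 0.0732). Over the settings and omissions these medians of 5 genes ranged from -2.86 to -0.76 and from -2.74 to -0.22, with the weakest values without the filter on dim probe sets. Of 16 unfolded protein response genes 7 were higher with SP600125 than with U0126 (median 0.48, adjusted p = 1.9e-05, and adjusted p = 0.104 with an estimated correlation). The other called lists lost their calls with an estimated correlation. They had medians of -0.09 for heat shock, -0.20 for unfolded protein response and 0.15 for ribosome biogenesis genes between SB203580 and SP600125. Between SB203580 and U0126 the medians were -0.15 for trophectoderm, -0.24 for epiblast, -0.26 for actin and -0.41 for amino acid response genes, and between SP600125 and U0126 -0.35 for epiblast and -0.47 for amino acid response genes.

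Single genes with the largest differences included BC080696 (-5.29 ± 0.42), Apoa1 (-4.57 ± 0.48) and Ctsll3 (-4.56 ± 0.57), all lower with SB203580 than with SP600125. Ttll11 (2.59 ± 0.44), the growth factor receptor gene Pdgfra of the primitive endoderm list (1.41 ± 0.15) and the carbonic anhydrase gene Car4 (1.29 ± 0.27) were higher. Between SB203580 and U0126, C8g (2.54 ± 0.47) and Rassf4 (2.18 ± 0.41) were higher, and Cyp1b1 (-3.76 ± 0.75), Cyp1a1 (-3.20 ± 0.62) and Ctsll3 (-2.60 ± 0.57) lower. Between SP600125 and U0126, AF067061 (4.81 ± 0.73), BC080696 (3.81 ± 0.42) and Gm20767 (3.55 ± 0.74) were higher, and Cyp1b1 (-4.05 ± 0.75), Cyp1a1 (-3.30 ± 0.62) and Amz1 (-2.53 ± 0.51) lower. Several of these genes had signals under the added constant, such as Cyp1b1 at 2.8 and 2.9 with SP600125 in replicates 2 and 3 and Gm20767 at 2.8 and 7.9 with U0126 in replicates 1 and 2. The sizes of such differences depend on that constant, and over the settings and omissions tried the SP600125 to U0126 difference ranged from -5.40 to -2.52 for Cyp1b1 and from 2.26 to 4.30 for Gm20767. For Cyp1a1, SB203580 replicate 1 differed by -0.44 from the U0126 mean of its array type, against -4.30 and -4.84 for replicates 2 and 3.

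SB203580 against SP600125 gave 212 probe sets (61 higher, 151 lower), SB203580 against U0126 378 (148 higher, 230 lower) and SP600125 against U0126 783 (384 higher, 399 lower). On the 430 2.0 arrays alone the counts were 113, 186 and 340, and 109, 177 and 308 of these moved the same way in replicate 1. SB203580 against SP600125 fell to 138, 106 and 102 without SB203580 replicate 1, 2 or 3 and to 140, 102 and 99 without SP600125 replicate 1, 2 or 3. SB203580 against U0126 gave 218, 147 and 154 without SB203580 replicate 1, 2 or 3 and 162 without U0126 replicate 3. SP600125 against U0126 gave 378, 424 and 367 without SP600125 replicate 1, 2 or 3 and 472 without U0126 replicate 3. Its balance turned to 198 higher and 180 lower without SP600125 replicate 1, and to 336 and 275, 362 and 361, and 247 and 225 without U0126 replicate 1, 2 or 3.

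Across the 3 inhibitors, Nsdhl, Amn and Csta1 fell in every comparison with control, and Krt19 and Ap5z1 rose. Over the 9 omissions of samples or replicates in each comparison, Krt19 kept its call in 0 for SB203580, 2 for SP600125 and 0 for U0126. Ap5z1 was called on 1 of its 5 probe sets for SB203580 and for U0126. Csta1, a cystatin gene outside the naming rule, was chosen after its values were seen (-1.04, -0.81 and -1.13). Because the 3 comparisons share controls, agreement between them was set beside simulations. The correlation of log2 changes across probe sets was 0.442 for SB203580 and SP600125, 0.429 for SB203580 and U0126 and 0.315 for SP600125 and U0126, against 0.5 simulated for unchanged groups, and probe sets are not independent replicates. Covariances were 0.0712, 0.0746 and 0.0546, against 0.0607, 0.0607 and 0.0606 simulated. Probe sets called lower in both numbered 9 for each pair, against 0 simulated and 0.26, 0.22 and 0.24 for independent lists, and those called higher in both numbered 6, 4 and 4, against 0, 0 and 0.01 simulated and 0.064, 0.043 and 0.13 for independent lists. The simulated groups held no changes and so gave almost no calls, and the independent value leaves out the shared controls, so the excess over either does not show a shared effect. Part of it may come from the shared controls, since 3 control samples cannot be divided into sets of 2 or more. Nabp1 was called in opposite directions, at 0.63 with SP600125 and -0.50 with U0126, and was named after its values were seen.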

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

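One of the settings given here, the one without probe sets ending in _x_at or _s_at, was chosen after seeing the data, as were the list tests between inhibitors. No called list or called named gene reversed its direction under these settings. The balance of higher and lower probe sets did turn for SP600125 against control, from 72 higher and 88 lower to 41 and 39 without replicate 1 and 46 and 40 without control replicate 1. For SP600125 against U0126 it turned from 384 and 399 to 402 and 364 with quantile normalisation and 306 and 294 without the filter, among other settings, so no direction is read from these 2 balances. The number of probe sets called depended on how the spread was estimated. Without the intensity trend in limma the counts dropped to 1 for SB203580, 8 for SP600125 and 2 for U0126 against control, and to 23, 41 and 135 for SB203580 against SP600125, SB203580 against U0126 and SP600125 against U0126. With array weights they were 202, 242 and 75 against control and 437 and 245 for SB203580 against SP600125 and U0126. With the filter at the 60th percentile U0126 against control gave 187. Here the cause was not tested, except that a stricter filter tests fewer probe sets. Quantile normalisation, other pseudocounts, no filter, the replicate block and leaving out _x_at and _s_at probe sets kept every count within 1.5 times. The replicate block gave 119, 180 and 150 against control, but same-numbered samples did not move together (correlations of replicate differences between groups 0.022 to 0.092 over 6 pairs), so numbers were not treated as pairs. Leaving out samples or whole replicates, which leaves fewer samples, gave ranges of 1 to 80 for SB203580, 16 to 92 for SP600125 and 2 to 117 for U0126 against control, and of 30 to 140, 7 to 323 and 107 to 723 for the direct comparisons in the order above. Where 1 sample per group was left within an array type, that sample was assumed to vary like the others.

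With an estimated correlation, camera called 4 lists for SB203580, 3 for SP600125 and 4 for U0126, in place of 7, 10 and 9, and every one of these had been called with the preset correlation. Leaving out samples gave 6 to 10 lists for SP600125, with 6 both without replicate 1 and without SP600125 replicate 1, and 6 to 9 and 8 to 10 for the others. List medians kept their signs, but many moved by more than 1.5 times, among them cleavage stage transcripts for SP600125 (1.14 to 2.32), G1 to S genes for U0126 (-0.32 to -0.12), and ERK output genes for SB203580 against U0126 (0.17 to 0.67). Among checks on lists and on the numbers of lists called between inhibitors, 1104 gave the same result, 84 lost a call and 3 numbers of lists moved. Among checks on the counts of probe sets and on the numbers of lists against control, 107 stayed within 1.5 times and 64 moved. Among checks on named genes, 2750 kept their side of the threshold, 642 lost a call and 29 gained one. Against control, the called named genes that held under every setting and omission in which they were tested were BC080696, Foxq1, Aqp8 and Col4a2 for SP600125 and Klk7 for U0126, and none did for SB203580. Between inhibitors they were Pdgfra, BC080696 and Apoa1 for SB203580 against SP600125, BC080696 for SP600125 against U0126, and none for SB203580 against U0126. Dim signals limit the largest changes. At least 1 sample lay under the added constant of 12.6 for the called genes Ap5z1, Ctsll3, Arhgap27, AF067061, Gm11544, Gm20767, Tcstv1, Cyp1a1, Cldn9, C8g, Cyp1b1, Ttll11, Rassf4 and Amz1, so the sizes of their changes depend on that constant.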

Other observations

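The tests on the lists of the Nodal and Wnt targets, on array scaling and on other splits of the samples were set out before their results were seen, and all other tests in this part were chosen after. A list of imprinted genes was drawn up after the rise of Grb10, a brake on insulin and growth factor signalling, had been seen with SP600125 (1.32 ± 0.19). Without Grb10 it had a median of 0.40 over 14 genes with that inhibitor (quartiles -0.10 and 0.87, camera adjusted p = 0.0213 over 12 added tests, and adjusted p = 0.452 with an estimated correlation). Phlda2, a gene that restrains placental growth (1.43 ± 0.23), rose, and the other 13 did not pass. The list's median was -0.05 with SB203580 (adjusted p = 0.919) and 0.40 with U0126 (adjusted p = 0.521), where the growth factor gene Igf2 fell (-1.13 ± 0.19, adjusted p = 0.0113).

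The call of Lefty1 with SB203580 held in 5 of 9 settings and 2 of 9 omissions, and that of Lefty2 in 8 of 9 and 4 of 9. Falls of Lefty1 and Lefty2 with SB203580 could follow from lower Nodal or TGF-beta signalling, since both are targets of that pathway. The other 7 tested targets had a median of -0.21 (quartiles -0.53 and -0.14, adjusted p = 0.461), with none past the test, so the question stays open. Falls of Dkk1 and Cdx1 with SB203580 and SP600125 could likewise follow from lower Wnt signalling. The other 7 tested targets had medians of -0.22 and -0.28 (adjusted p = 0.461 and 0.315), with none past the test, and this stays open as well. With SB203580, Dkk1 was called on 1 of its 2 probe sets. High control libraries were not weighed here. On that probe set Dkk1 signals were also lower with U0126 (498.8, 229.4 and 336.9) than in controls (1643.1, 475.7 and 564.6). Cdx1 signals were 355.6, 334.9 and 317.6 with U0126 and 261.9, 518.3 and 305 in controls.

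The fall of primitive endoderm markers with SP600125 was weighed against RNA quality, embryo composition, scaling and the controls. Loss of 5' signal in SP600125 replicate 1 is argued against as the whole cause by the weaker median of the 430 2.0 arrays, -1.06. The epiblast list had a median of -0.02 (quartiles -0.18 and 0.08). This argues against a smaller share of inner cell mass cells only where epiblast cells were lost as well. The epiblast list cannot show whether primitive endoderm cells alone became fewer within the inner cell mass, which was not tested. Quantile normalisation left the median at -1.24. High control libraries as the whole cause would leave SP600125 level with U0126 and with SB203580. The direct difference from U0126 was -0.57 (camera adjusted p = 0.00188, fry adjusted p = 0.00757), and SB203580 stood 0.59 above SP600125 (camera adjusted p = 6.03e-06, fry adjusted p = 0.00399). With an estimated correlation the adjusted p = 0.149 and 0.0775, so this stays open for the list. Controls do not enter the direct differences. Of 21 markers, 3 were called higher with SB203580 than with SP600125, or 10 higher and 1 lower adjusted over the list alone. Pdgfra, which differed by 1.41 ± 0.15, was called under every setting. High controls do not account for these called differences, but these members do not decide for the list. A call with the estimated correlation was the criterion of a first run, was replaced by camera and fry calls after its value was known, and was then restored. For the fall common to the 3 inhibitors, with medians of -0.51 or lower in each, high control libraries and a biological effect of each inhibitor cannot be told apart, because all 3 comparisons use the same controls. A difference in solvent between the controls and all treated groups cannot be told apart from these either, since the labels do not state it.

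The rise of cleavage stage transcripts with SP600125 did not come from a single library, as the lowest replicate median was 1.42, nor from scaling, as quantile normalisation left 1.91. Only 7 of the 16 listed transcripts passed the signal filter in the main test, and that filter includes the SP600125 arrays. Embryos arrested at early stages among the blastocysts could bring such transcripts. The list of oocyte and maternal transcripts had a median of -0.12 with members in both directions, which does not decide it, since the stage of an arrest would set which maternal transcripts remain. An arrest and a change of these genes within blastocysts cannot be told apart here.

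The fall of cholesterol synthesis genes with SB203580 and SP600125 was weighed against high control libraries and scaling. Against U0126, which leaves the controls out, the weaker median was -0.36 (camera adjusted p = 4.35e-06, fry adjusted p = 0.00322), and the other was -0.44 (fry adjusted p = 0.00328), but with an estimated correlation, the same restored criterion, the adjusted p = 0.0613 and 0.0751. Of 19 genes, 3 were called lower with SB203580 than with U0126, and 6 with SP600125. High controls do not account for those differences. By the restored criterion, high control libraries and an effect of the compounds cannot be told apart for the list as a whole. Scaling as the whole cause is argued against by the weaker median against control with quantile normalisation, -0.48.

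Each comparison of 3 against 3 samples has 10 splits, which cannot give a share under 0.05. In 1 of 10 splits, the real one, the counts were 105, 160 and 123 probe sets against control and 212, 378 and 783 between inhibitors, and the highest of the other splits was 0 in all 6. For lists the real values were 7, 10 and 9 for SB203580, SP600125 and U0126, again reached in 1 split each, and the highest others were 3, 6 and 6. The other splits mix samples of both groups, so any difference between the groups enters their spread. They therefore do not show how many calls unchanged groups would give.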
